A study of Mus musculus with 15 samples.

How the data were processed

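Bulk RNA-seq was made from mouse skeletal muscle stem cells, also called satellite cells, the resident stem cells of muscle fibres. The labels name 6 bulk time points, T0, T15, T30, T60, T90 and T120, and give no unit for these numbers, which were taken as minutes. T0 is labelled as intact tissue and the later points as dissociated tissue, and all 6 are labelled as fixed. Per the labels' protocols, fixation was with PFA and dissociation with a collagenase and dispase mixture, which digests the matrix around cells. Per the labels' protocols, bulk RNA was extracted with a kit made for formalin-fixed samples, turned into stranded total RNA libraries with a low-input SMARTer kit and read on an Illumina HiSeq instrument as 65-base single reads. How the bulk cells were sorted is not given in the sources used here. The labels list 15 samples, of which 9 (6 of single nuclei and 3 of single cells) have no file here and were not analysed here.

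The deposited table gives, per the file headers, whole-number counts per Ensembl gene for 22 libraries: 4 each at T0, T15, T60 and T120, and 3 each at T30 and T90. Libraries are named by the letters A to D of the table. Per the submitters' processing notes, the tools named for the series include cutadapt 1.11, featureCounts 1.4.5-p3 and DESeq2 1.18.1, and the build is mm10. Those notes give no role or order, and also name Cell Ranger 3.0.2 and Seurat 3.0.2, which belong to single-cell data. The aligner, the annotation release, and whether counting used strand are not given in the sources used here. A second set of columns holds counts that the authors divided by 1 size factor per library and rounded, a score rather than a count. It equals the counts over the recovered factor within 0.59 and served only as an alternative scaling. The table also holds the authors' log2 fold changes and adjusted p-values for 15 comparisons, per the file headers. They were set beside the values computed here. A further 21 columns, 6 group means and 15 linear fold changes by the authors, were not used. All columns of single libraries that were used matched a time point of the labels, and 0 were left unmatched.

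The table lists 8059 genes, and every listed gene has an adjusted p in all 15 of the authors' comparisons. Its lowest mean normalized count over all libraries, as the authors give it, is 98.4, so weakly expressed genes are not in it. A total of 557 listed genes have no authors' adjusted p under 0.05, so the list was not restricted to changed genes. Because part of each library is outside the table, the column totals are totals over listed genes and not sequencing depth. They ran from 2974294 to 10482407 counts at T0, T15 and T30 and from 8647622 to 27826437 counts at T60, T90 and T120. Of the identifiers, 8049 matched the GENCODE vM21 annotation of GRCm38 (mm10), which gave names, positions and exon lengths. Positions are 1-based. By that annotation 7641 genes are protein coding and 0 are mitochondrially encoded.

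Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with TMM factors and Benjamini-Hochberg adjustment over the listed genes. Genes with an adjusted p under 0.05 were called. The 22 libraries shared a fit with time point as a factor, a common biological coefficient of variation of 0.192, and no covariate. Low-count filtering with filterByExpr kept all 8059 genes. TMM scaling takes most genes as unchanged, while from T60 on 56.2% to 76.8% of the listed genes were called. A shift shared by most genes could thus not be seen. The scaling favours even numbers of rises and falls, and small fold changes depend on it. Each later point was compared with T0, a joint F test asked whether a gene changed at any time, and a separate fit gave a slope of log2 expression per hour. Steps between neighbouring time points were added after the data were seen. They avoid the shared T0 libraries, which give the 5 comparisons with T0 part of the same chance values. Neighbouring steps share a time point with opposite sign, so they are not independent either. Levels are CPM (counts scaled to the library total) with TMM factors, as mean ± SD over libraries, and fold changes are log2 ± standard error (SE), with the SE taken as the size of the log2 fold change over the square root of F. Every adjusted p below is from this edgeR test unless another is named.

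A set of 28 gene lists was fixed before the data were examined, as were the design and most alternatives. Of these, 23 had at least 3 listed members and were tested with camera from limma 3.58.1, with a preset correlation of 0.01 and log CPM at a prior count of 2. The p-values were adjusted over the 115 list tests against T0. Of these tests 49 were called, and 17 with a correlation estimated from the data. List tests after background subtraction were run with the preset correlation only. For the step comparisons the list tests were adjusted as a separate family. The lists under 3 members were immune, tenocyte, glial, erythroid and mitochondrially encoded genes. Some lists share members, so their tests are not independent. Dusp1 is in the immediate early and MAP kinase feedback lists, and Ccn1 and Ccn2 are in the immediate early and YAP and cytoskeleton lists. The list of cytosolic ribosomal proteins follows a symbol rule that also took kinases of the Rps6k family and Rps19bp1. A version without those members was added later and the number of called list tests stayed at 49. Genes are named by a rule fixed in advance. It takes the genes with the largest changes in each comparison that were called, had a mean of at least 10 CPM and did not overlap T0 in any library (a condition not used for the slope), leaving out 405 predicted models. It also takes up to 4 members of each list with the largest change at T120, members that went against their list, and a set of genes named in advance.

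Some long genes known mainly from other tissues had counts that moved together across early libraries. A background density was therefore measured as the median count per kb of exon over 9 such genes, the listed ones among 50 genes chosen after the data were seen. Of the 50, 4 had been noticed in the data and the others were taken from general knowledge of cilia, sense organs, brain and gut. Of the 9, Ryr3, a calcium release channel gene that muscle can also express, was at 5.47 to 25.6 CPM per kb in all libraries and so was not silent. Only genes dense enough to be listed could enter, so the density is more an upper bound than an estimate. Alternatives subtracted exon length times this density, 0.5 of it, or the density without Ryr3 from the counts, or left out the 5 libraries with the highest density. Counts that the subtraction took below 0 were set to 0. A weak long gene could so lose all counts in a group, and its fold change then says little about size. Subtraction also raised the common coefficient of variation from 0.192 to 0.309. A call could thus be lost after subtraction without a smaller fold change. Other alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors within edgeR, the authors' size factors, no filter, a mean of at least 10 counts, no ribosomal and small RNA genes (116 genes), the library letter as a block (also with T60, T90 and T120 alone), T0 with 1 time point alone, the slope on the order of time points, as a spline, without T0 or without T120, and each library left out in turn. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

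The procedure was tested on counts simulated from the T0 means, the estimated dispersions and the real library sizes. For T15 against T0 it recovered 24 of 80 genes changed 1.5-fold, 56 of 63 changed 2-fold and 57 of 57 changed 4-fold, with 6 false calls. For T120 against T0 the values were 20 of 62, 68 of 74 and 64 of 64, with 5 false calls. Few genes were changed in these runs, in random directions and with no difference in background. In the data 56.2% to 76.8% of the listed genes were called from T60 on. These runs therefore do not give the recovery or the false calls to be had at T60, T90 and T120. A further simulation added 20 counts per kb to early libraries and 1 to late ones with 0 genes truly changed. The T120 test then called 448 genes up and 785 down, and after subtraction 0 up and 2 down. The background genes held only the added density there, equal in all early libraries, so the subtraction had to recover it. In the data the density ran from 7.09 to 18.3 counts per kb over the T0 libraries and Ryr3 was not silent. The simulation therefore does not show how well the subtraction worked on the data. Replicate libraries differed by far more than counting noise, with a lowest chi-square per gene of 12.3 between libraries of a time point, and 0 columns were identical. Among T60, T90 and T120, libraries with a shared letter deviated together: all 10 such pairs had a correlation of deviations from the group means over 0.1 (0.17 to 0.467), against 6 of 30 pairs with other letters. This hint of pairing comes from the data and not from the labels. The labels do not say whether the libraries of a time point came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.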

Results

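The 22 libraries followed muscle stem cells from intact tissue (T0) through tissue dissociation of up to 120 minutes. The first principal component of log CPM held 66.5% of the variance and the second 11.2%. The T0, T15 and T30 libraries lay on one side of the first component and those of T60, T90 and T120 on the other. Genes called against T0 numbered 54 at T15, 403 at T30, 4533 at T60, 5546 at T90 and 6187 at T120, of 8059 listed. In order of time these were 0.67%, 5%, 56.2%, 68.8% and 76.8% of the listed genes. Counts of called list members have to be read beside these shares, above all from T60 on.

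**Figure D1:**
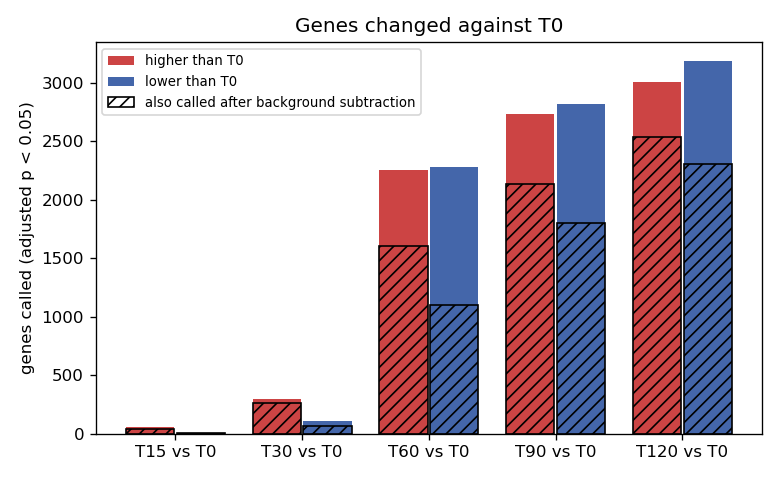
Genes called higher or lower than T0 at each time point (edgeR, adjusted p under 0.05), by direction. The hatched part of each bar was also called in the same direction after subtraction of the background density measured in 9 long genes.

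At T15 the AP-1 and EGR transcription factor genes, which respond to signalling without new protein synthesis, were the most raised genes. Fosb went from 10.1 ± 5.49 CPM at T0 to 2030 ± 492 CPM (4 libraries each), a log2 fold change of 7.71 ± 0.42 (adjusted p = 7.2e-11). Fos rose by 7.36 ± 0.44, Egr1 by 5.78 ± 0.28, Junb by 5.25 ± 0.29 and Jun by 4.44 ± 0.36 (adjusted p = 2.48e-10, 2.07e-11, 7.2e-11 and 3.96e-08). Nr4a1, an orphan nuclear receptor, rose by 4.21 ± 0.35 and Ier2 by 4.12 ± 0.23. Also raised were Btg2 (3.73 ± 0.23), an antiproliferative factor, Socs3 (3.57 ± 0.31), an inhibitor of cytokine signalling, Zfp36 (3.46 ± 0.22), which promotes decay of AU-rich mRNAs, and Dusp1 (3.07 ± 0.17), a MAP kinase phosphatase.

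Of 33 measured immediate early genes, 20 were up at T15 and 0 down (26 up when adjusted over the list alone), with camera adjusted p = 1.44e-266 and adjusted p = 7.9e-08 with an estimated correlation. Among NF-kB and cytokine genes 3 of 16 rose (6 adjusted over the list alone), including the chemokine gene Cxcl1 (2.4 ± 0.47). The camera adjusted p was 1.4e-09, and adjusted p = 0.0517 with an estimated correlation. Among the stress genes of translation and protein folding 2 of 19 rose (5 adjusted over the list alone; camera adjusted p = 5.19e-09, and 0.00143 with an estimated correlation). These were Ppp1r15a (2.29 ± 0.19), which helps to restart translation, and Atf4 (0.79 ± 0.13), a transcription factor of the integrated stress response. After background subtraction Atf4 had 0.7 (adjusted p = 0.0953) and was not called. Of the MAP kinase feedback genes 1 of 15 rose, Dusp1, which is in the immediate early list as well (4 adjusted over the list alone; camera adjusted p = 2.08e-11, and 4.32e-05 with an estimated correlation). Of the YAP and cytoskeleton genes 2 of 18 rose, among them Ccn1 (3.04 ± 0.24), which is in the immediate early list too (3 adjusted over the list alone; camera adjusted p = 1.47e-10, and 0.0223 with an estimated correlation).

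The inducible heat shock genes Hspa1a (3.36 ± 0.55) and Hspa1b (2.62 ± 0.54) were the members called of 21 in the heat shock list (4 adjusted over the list alone). Reads of these near-identical genes are hard to tell apart. The camera adjusted p was 0.000325, and adjusted p = 0.265 with an estimated correlation. The glucocorticoid response list had 1 of 11 members up, the kinase gene Sgk1 (0.81 ± 0.17), and 3 adjusted over the list alone (camera adjusted p = 0.000223, and adjusted p = 0.237 with an estimated correlation). Of the satellite cell quiescence genes 0 of 35 were called, over all genes or adjusted over the list alone, while camera placed the list upward (median log2 fold change 0.15; adjusted p = 0.00155, and adjusted p = 0.357 with an estimated correlation), a call lost after background subtraction. Camera also placed the circadian list upward with 0 of 16 called (2 adjusted over the list alone; adjusted p = 0.00955, and adjusted p = 0.174 with an estimated correlation). It placed the 7 endothelial markers downward with 0 called, also when adjusted over the list alone (adjusted p = 0.00221, and adjusted p = 0.357 with an estimated correlation), and this call, too, was lost after background subtraction. Pax7, the transcription factor that marks satellite cells, had a log2 fold change of 0.08 ± 0.16, and Myod1, the myogenic determination factor, 0.03 ± 0.19.

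In all, 53 genes were up and 1 down at T15, and 37 of the raised ones at least 2-fold. The gene called down was Gm43362 (-0.87 ± 0.17; adjusted p = 0.00767), a predicted model named here after its value was seen. A total of 265 genes had an unadjusted p under 0.05. Of the other ways to split these libraries into 2 groups of 4, a pair called as many genes or more, 61 and 86.

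At T30 the fold changes of the same transcription factor genes against T0 were larger in value, which is no test of the step from T15. Fosb was raised by 8.7 ± 0.44, Fos by 8.4 ± 0.47, Egr1 by 6.88 ± 0.3, Junb by 6.24 ± 0.31 and Nr4a1 by 5.7 ± 0.38 (3 libraries at T30). Atf3, a stress-induced transcription factor, rose by 4.8 ± 0.38 and Socs3 by 5.28 ± 0.34. Gadd45b (3.06 ± 0.34) and Cdkn1a (2.3 ± 0.33), which encodes the cell cycle inhibitor p21, were raised as well, as was the metallothionein gene Mt1 (1.88 ± 0.25). Fallen genes included 3 known targets of the glucocorticoid receptor: Tsc22d3 (-2.19 ± 0.45; adjusted p = 0.00369), Zbtb16 (-1.84 ± 0.24; adjusted p = 2.57e-05) and Fkbp5 (-1.77 ± 0.3; adjusted p = 0.000538). The glucocorticoid response list as a whole had 3 of 11 down and 0 up (2 up and 4 down adjusted over the list alone) and was not called (camera adjusted p = 0.118, and adjusted p = 0.713 with an estimated correlation). After background subtraction it had 3 up and 3 down. Ttyh1 (-1.55 ± 0.35), the surface glycoprotein gene Thy1 (-1.34 ± 0.3), the clock output genes Dbp (-1.24 ± 0.33) and Tef (-0.76 ± 0.19), and Foxo3 (-0.79 ± 0.21), a transcription factor linked to stem cell quiescence, fell too.

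By list, 29 of 33 immediate early genes were up at T30 and 0 down (30 adjusted over the list alone; camera adjusted p = 1.36e-172, and 1.1e-06 with an estimated correlation). Of NF-kB and cytokine genes 10 of 16 rose (13 adjusted over the list alone; camera adjusted p = 1.27e-23, and 0.00316 with an estimated correlation), among them Cxcl1 (3.9 ± 0.48), Bcl3 (1.75 ± 0.28) and Nfkbia (1.04 ± 0.22). YAP and cytoskeleton genes had 8 of 18 up (11 adjusted over the list alone; adjusted p = 8.4e-11, and 0.0223 with an estimated correlation), with Ccn1 at 4.68 ± 0.26 and Thbs1 at 1.76 ± 0.33. The stress genes of translation and protein folding had 7 of 19 up (7 adjusted over the list alone; 9.31e-07, and 0.0051 with an estimated correlation). MAP kinase feedback genes had 4 of 15 up (7 adjusted over the list alone; 7.35e-07, and 0.000944 with an estimated correlation).

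Weaker list results at T30 were as follows. Oxidative stress genes had 4 of 16 up (4 up and 1 down adjusted over the list alone; adjusted p = 0.0114, and adjusted p = 0.221 with an estimated correlation). Genes regulated by p53 had 4 of 14 up (5 up and 2 down adjusted over the list alone; adjusted p = 0.0306, and adjusted p = 0.154 with an estimated correlation), and the list was not called after background subtraction. Smooth muscle and pericyte markers had 1 of 8 up (1 adjusted over the list alone; adjusted p = 0.0452, and adjusted p = 0.208 with an estimated correlation). That member, Des (0.88 ± 0.15), is a muscle gene as well. Heat shock genes had 7 up and 1 down of 21 (7 up and 4 down adjusted over the list alone), with a median of -0.09, a mean of 0.59 and camera adjusted p = 0.0622 (0.661 with an estimated correlation). With the preset correlation the list was called upward after background subtraction, with 7 up and 0 down. Cytosolic ribosomal protein genes had 1 of 85 up (1 adjusted over the list alone) and a median of -0.24, and camera placed them downward (adjusted p = 0.00373, and adjusted p = 0.713 with an estimated correlation), but not after background subtraction. The immune marker Cd68 rose by 1.72 ± 0.34 (adjusted p = 0.00298).

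In total 295 genes rose and 108 fell at T30, and 152 and 10 of these changed at least 2-fold. With the authors' size factors the split was 437 up and 41 down. The number of falls hung on single libraries: it was 31 without 30A, 27 without 30B and 191 without 30C. The rises numbered 213, 250 and 374 in these runs. Without library 30A the number called was 244, without the 5 libraries of highest background, which leaves T30 with 1 library, 147, and after background subtraction 664.

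Taken directly, T30 against T15 gave 255 genes up and 139 down. Tnfrsf12a, the receptor of the cytokine TWEAK, rose by 1.93 ± 0.19 (adjusted p = 1.02e-05) and Zfp36 by 1.68 ± 0.21, while Zbtb16 fell by 1.93 on the log2 scale (SE 0.24; adjusted p = 7.06e-05) and Fkbp5 by 1.90 (SE 0.3). Immediate early genes had 16 of 33 up (25 up and 1 down adjusted over the list alone; adjusted p = 5.84e-23, and adjusted p = 0.0693 with an estimated correlation). This number of called genes hung on single libraries: it was 107 without 30A and 1140 without 15D. DESeq2 called 647, limma-voom 260, and 69 were called without the 5 libraries of highest background, which again leaves T30 with 1 library.

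Between T30 and T60 the libraries changed in a second way. At T60 the genes with the largest falls against T0 were Muc16 (-10.85 ± 2.02), Mroh2a (-7 ± 1.24), Ntrk3 (-5.98 ± 1.13), Sp110 (-5.36 ± 0.9) and Pclo (-4.41 ± 0.78), of which Muc16 is an epithelial mucin gene and Pclo a presynaptic one. Of these, Muc16, Mroh2a and Pclo are among the 9 long genes used to measure the background. After background subtraction Muc16 and Ntrk3 no longer had enough counts to be tested. The background density was 2.56 ± 1.17 CPM per kb at T0, 1.73 ± 1.69 at T15 and 4.47 ± 2.7 at T30, against 0.126 ± 0.0238 at T60, 0.216 ± 0.169 at T90 and 0.384 ± 0.45 at T120. Without Ryr3, which had counts at every time, the means were 2.5, 1.69, 4.33, 0.118, 0.177 and 0.359 in order of time. In single libraries it came to between 7.24% (15B) and 63.1% (30A) of the density of the median listed gene up to T30, and to between 1.14% (60D) and 11.7% (120B) later.

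**Figure D2:**
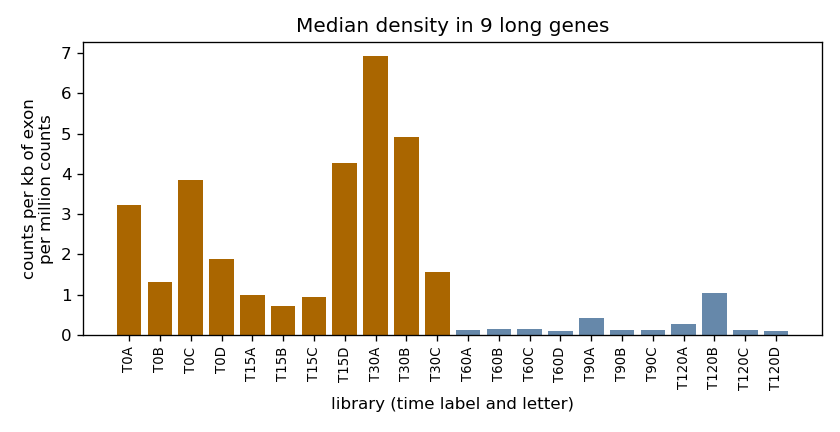
Background density in each library, the median CPM per kb of exon over 9 long genes. Libraries of T0, T15 and T30 carried more than those of T60, T90 and T120, except that 120B exceeded 15A, 15B and 15C.

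At T60 the early transcription factor genes were still high: Fosb 9.18 ± 0.44, Fos 8.1 ± 0.46, Junb 6.81 ± 0.31, Egr1 6.77 ± 0.29 and Nr4a1 6.76 ± 0.39 over T0. Many further genes had risen. They included Csrnp1 (6.5 ± 0.38), Tnfrsf12a (5.84 ± 0.21), Trib1 (4.79 ± 0.23), Bcl3 (4.45 ± 0.27), the co-chaperone gene Bag3 (3.36 ± 0.18), Errfi1 (3.23 ± 0.21), which encodes a brake on EGF receptor signalling, and Txnrd1 (2.71 ± 0.15), a thioredoxin reductase gene. Myc, the growth-promoting transcription factor, rose by 1.83 ± 0.19 (adjusted p = 1.15e-07), from 154 ± 33.7 to 549 ± 109 CPM. Pax7 (0.24 ± 0.16) and Myod1 (0.24 ± 0.19) were not called (adjusted p = 0.204 and 0.303).

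Lists that were up at T60 included immediate early genes (32 of 33, also adjusted over the list alone; camera adjusted p = 6.79e-49, and 0.00143 with an estimated correlation). Of NF-kB and cytokine genes 14 of 16 rose (14 adjusted over the list alone; 3.89e-13, and 0.0225 with an estimated correlation). Stress genes of translation and protein folding had 12 up and 1 down of 19 (13 up and 2 down adjusted over the list alone; 1.72e-08, and 0.00199 with an estimated correlation), and MAP kinase feedback genes 10 of 15 up (10 adjusted over the list alone; 0.000144, and 0.0051 with an estimated correlation). YAP and cytoskeleton genes had 15 of 18 up (15 adjusted over the list alone; adjusted p = 2.46e-07, and adjusted p = 0.0517 with an estimated correlation), and oxidative stress genes 11 up and 1 down of 16 (the same adjusted over the list alone; adjusted p = 1.72e-05, and adjusted p = 0.0517 with an estimated correlation). Heat shock genes had 12 up and 2 down of 21 (the same adjusted over the list alone; adjusted p = 0.000294, and adjusted p = 0.265 with an estimated correlation).

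Some lists of growth and differentiation genes were called at T60 with the preset correlation and not with an estimated one. Of the myogenic commitment genes 9 of 13 rose (9 adjusted over the list alone; adjusted p = 0.00576, and adjusted p = 0.208 with an estimated correlation), among them Des (1.7 ± 0.14), already raised at T30, and Msc (1.03 ± 0.18). Ribosome biogenesis genes had 13 up and 1 down of 23 (the same adjusted over the list alone; adjusted p = 0.0209, and adjusted p = 0.713 with an estimated correlation), with Nop58 at 2.28 ± 0.16. After background subtraction this list had 8 up and 3 down and was not called. Glycolysis genes had 9 up and 2 down of 14 (the same adjusted over the list alone; adjusted p = 0.0465, and adjusted p = 0.142 with an estimated correlation), with Hk2 at 2.41 ± 0.29, and 5 up and 1 down after background subtraction, still called. The myofibre markers had 6 of 10 down (6 adjusted over the list alone; adjusted p = 0.232), among them the long genes Ttn (-1.51 ± 0.31) and Ryr1 (-1.13 ± 0.22). After background subtraction 2 of 10 were down, and Ttn had -0.21 (adjusted p = 0.83) and Ryr1 -0.78 (adjusted p = 0.0441).

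T60 against T0 called 2252 genes up and 2281 down, with 764 and 608 at least 2-fold. After background subtraction, which also raised the common coefficient of variation between libraries from 0.192 to 0.309, 1601 of the raised and 1098 of the fallen genes were still called in the same direction, and 2055 and 1853 after subtraction of 0.5 of it. Against T30 instead of T0, 2137 genes were up and 1974 down. That step called 2370 genes after subtraction and 1619 without the 5 libraries of highest background, where T30 keeps a single library assumed to vary like the others.

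At T90 the balance of the 2 myogenic factors had shifted. Myod1 had risen by 2.1 ± 0.21 (adjusted p = 2.09e-08), from 81.5 ± 14.5 CPM at T0 to 350 ± 130 CPM in 3 libraries, and Pax7 had fallen by 0.67 on the log2 scale (SE 0.17; adjusted p = 0.0018). Spry1, an inhibitor of growth factor signalling that is kept on in quiescent satellite cells, fell by 1.61 (SE 0.24), the Notch effector gene Hes1 by 1.53 (SE 0.35) and Gas1 by 2.04 (SE 0.29). Some of the genes raised early were lower than at T60, among them Jun (-2.1 ± 0.36), Fos (-1.94 ± 0.37), Socs3 (-1.45 ± 0.3) and Egr1 (-0.99 ± 0.25). Fosl1, another AP-1 gene, rose in that step by 2.28 ± 0.44 and Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, by 3.2 ± 0.47.

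Against T0 the most raised genes at T90 were Fosb (7.96 ± 0.43), Csrnp1 (6.63 ± 0.39), Fosl1 (6.59 ± 0.57), Tnfrsf12a (6.35 ± 0.21) and Fos (6.17 ± 0.43). The most fallen were Muc16 (-6.18 ± 1.52), Mroh2a (-5.48 ± 1.24), Sp110 (-5.2 ± 1), Sfi1 (-4.63 ± 0.94) and Ntrk3 (-4.34 ± 1.12), beside a background density of 2.56 at T0 and 0.216 at T90. Muc16 and Ntrk3 could not be tested after background subtraction. Immediate early genes had 32 of 33 up (32 adjusted over the list alone; adjusted p = 2.02e-24, and 0.0166 with an estimated correlation). Stress genes of translation and protein folding had 13 up and 1 down of 19 (the same adjusted over the list alone; 7.33e-06, and 0.00632 with an estimated correlation), and MAP kinase feedback genes 12 up and 2 down of 15 (the same adjusted over the list alone; 0.00288, and 0.0223 with an estimated correlation).

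Other lists were up at T90 only with the preset correlation. They were NF-kB and cytokine genes (15 of 16 up, also adjusted over the list alone; adjusted p = 9.31e-07, and adjusted p = 0.119 with an estimated correlation), oxidative stress genes (12 up and 2 down of 16, the same adjusted over the list alone; adjusted p = 3.37e-05, and adjusted p = 0.0517 with an estimated correlation) and heat shock genes (14 up and 1 down of 21, 15 up and 1 down adjusted over the list alone; adjusted p = 0.000144, and adjusted p = 0.237 with an estimated correlation). YAP and cytoskeleton genes had 14 up and 2 down of 18 (the same adjusted over the list alone; adjusted p = 0.000223, and adjusted p = 0.174 with an estimated correlation). Ribosome biogenesis genes had 17 of 23 up (17 adjusted over the list alone; adjusted p = 0.000625, and adjusted p = 0.517 with an estimated correlation). Myogenic commitment genes had 9 of 13 up (9 adjusted over the list alone; adjusted p = 0.000746, and adjusted p = 0.126 with an estimated correlation). Replication-dependent histone genes had 7 of 8 down (7 adjusted over the list alone; adjusted p = 0.0294, and adjusted p = 0.494 with an estimated correlation).

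T90 against T0 called 2727 genes up and 2819 down, 1303 and 1224 of them at least 2-fold. After background subtraction 2132 and 1800 were still called in the same direction, and 2583 and 2526 after subtraction of 0.5 of the background. The step from T60 called 1347 up and 1094 down, 1621 in all without library 90A and 1217 in all after subtraction.

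At T120 the change from Pax7 to Myod1 had gone further. Pax7 (chromosome 4, 139737062 to 139833528) went from 1340 ± 203 to 377 ± 80.8 CPM, a log2 fold change of -1.83 ± 0.16 (adjusted p = 2.54e-09). Myod1 (chromosome 7, 46376474 to 46379099) went from 81.5 ± 14.5 to 936 ± 93.6 CPM, a log2 fold change of 3.52 ± 0.21 (adjusted p = 8.32e-12). Both also changed in the step from T90, Pax7 by -1.16 ± 0.17 (adjusted p = 0.000211) and Myod1 by 1.42 ± 0.21 (adjusted p = 0.000245). Myc stood at 1220 ± 92.3 CPM (2.99 ± 0.2 over T0), while Myf5, another myogenic factor, had 0.25 ± 0.17 (adjusted p = 0.181).

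**Figure D3:**
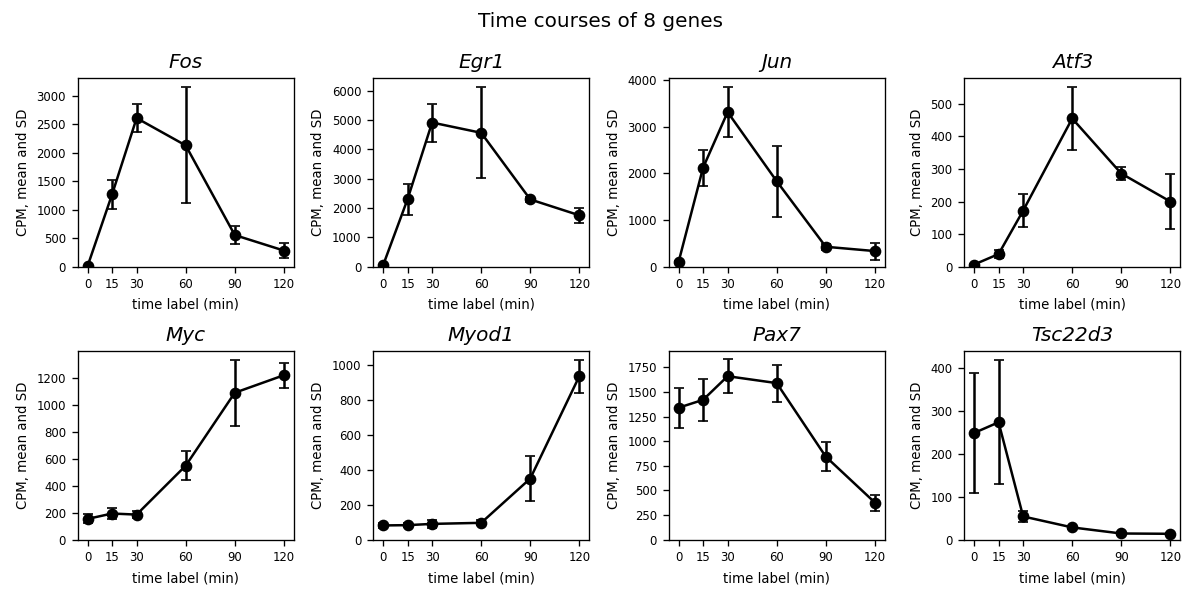
CPM (mean and SD over libraries) of Fos, Egr1, Jun, Atf3, Myc, Myod1, Pax7 and Tsc22d3 at each time point. Fos, Egr1 and Jun were highest at T30, Atf3 at T60, and Myc and Myod1 at T120.

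Genes with the largest rises at T120 were the AP-1 genes Fosl1 (7.4 ± 0.57; adjusted p = 3.16e-10) and Fosb (6.6 ± 0.4), then Hspa1a (6.44 ± 0.55), Tnfrsf12a (6.4 ± 0.21), Hspa1b (6.31 ± 0.54), Hmox1 (6.25 ± 0.52; adjusted p = 8.05e-10), Csrnp1 (6.1 ± 0.38), Emp1 (5.44 ± 0.27), Fgl2 (5.44 ± 0.4), Ier5 (5.4 ± 0.4), Egr1 (5.39 ± 0.27) and Asb5 (5.34 ± 0.26). Hmox1 was at 4.07 ± 1.19 CPM at T60, 37.9 ± 34.6 at T90 and 353 ± 102 at T120. Genes with the largest falls were Bmyc (-4.21 ± 0.28), a relative of Myc, Tsc22d3 (-4.19 ± 0.44), Nctc1 (-4.09 ± 0.2), Dbp (-3.7 ± 0.34), Zkscan8 (-3.59 ± 0.28), and G0s2 (-3.53 ± 0.36), which encodes an inhibitor of fat breakdown. Traf3ip3 (-3.39 ± 0.17), Pik3ip1 (-3.38 ± 0.3), an inhibitor of PI3 kinase, Tex9 (-3.35 ± 0.34), Muc16 (-3.35 ± 1.12), Fam13a (-3.34 ± 0.4) and Fbxw17 (-3.34 ± 0.37) followed. Muc16 is among the background genes, and the background density was 2.56 at T0 and 0.384 at T120.

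Of the satellite cell quiescence genes 18 fell and 8 rose of 35 at T120 (the same adjusted over the list alone), with a median of -0.34 and camera adjusted p = 0.206 (0.815 with an estimated correlation). After background subtraction 21 fell and 5 rose, and camera with the preset correlation called the list downward. Those that fell included Gas1 (-3.32 ± 0.28), Foxo3 (-1.98 ± 0.2), Pax7, Spry1 (-1.7 ± 0.21) and Calcr (-0.79 ± 0.14), which encodes the calcitonin receptor. Those that rose included Sdc4 (2.59 ± 0.18), a heparan sulfate proteoglycan gene, Fgfr1 (1.83 ± 0.15), Cxcr4 (0.79 ± 0.15), Itga7 (0.77 ± 0.17), Notch1 (0.76 ± 0.14), Chrdl2 (0.52 ± 0.18), Col5a1 (0.42 ± 0.12) and Tek (0.4 ± 0.17), of which Chrdl2, Col5a1 and Tek were not called after background subtraction. In the step from T90 the list had 15 down and 1 up (16 down and 1 up adjusted over the list alone; adjusted p = 0.000289, and adjusted p = 0.44 with an estimated correlation). Notch targets had 6 of 7 down (6 adjusted over the list alone; adjusted p = 0.0543, and 0.237 with an estimated correlation, and 6 down and called with the preset one after background subtraction), with Dtx4 at -2.44 ± 0.12, Hes1 at -1.9 ± 0.33, Dll1 at -1.33 ± 0.23 and Heyl at -0.71 ± 0.14. The cell cycle inhibitor genes Cdkn1b (-0.34 ± 0.17; adjusted p = 0.074) and Cdkn1c (0.15 ± 0.56; adjusted p = 0.81) were not called, but Cdkn1b was called down after background subtraction (-0.54).

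Myogenic commitment genes had 9 up and 3 down of 13 (the same adjusted over the list alone; adjusted p = 0.00169, and adjusted p = 0.156 with an estimated correlation). Msc (2.92 ± 0.19) and Des (1.7 ± 0.14) rose, and Myog (-3.15 ± 0.97), a factor of terminal differentiation, Rbm24 (-1.01 ± 0.31; not called after background subtraction) and Ncam1 (-0.33 ± 0.11) fell. Ribosome biogenesis genes had 22 of 23 up (22 adjusted over the list alone; median 1.68; adjusted p = 1.37e-06, and adjusted p = 0.296 with an estimated correlation), with Nop58 at 2.55 ± 0.16, Nolc1 at 2.46 ± 0.11 and Ddx21 at 2.23 ± 0.15. Cytosolic ribosomal protein genes had 39 up and 3 down of 85 (34 up and 3 down adjusted over the list alone; adjusted p = 0.0304, and adjusted p = 0.815 with an estimated correlation). After background subtraction they had 23 up and 3 down and the list was not called. The members that fell before subtraction were the kinase genes Rps6kc1, Rps6ka5 and Rps6ka4, which are not ribosomal proteins, and afterwards Rps6ka5 and Rps6ka4 were not called. Of the cell cycle genes 7 fell and 1 rose of 14 (6 and 1 adjusted over the list alone; adjusted p = 0.384). Ccnd3 (-2.01 ± 0.2), Mcm2 (-1.63 ± 0.4) and Ccnd1 (-1.14 ± 0.31) fell, and Pcna (1.52 ± 0.19), the replication clamp, rose. After background subtraction 3 fell and 1 rose, and Mcm2 was not called.

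Stress lists stayed up at T120. Heat shock genes had 19 of 21 up (19 adjusted over the list alone; adjusted p = 5.44e-06, and adjusted p = 0.174 with an estimated correlation), with Bag3 at 3.84 ± 0.18 and Hsph1 at 3.35 ± 0.22. Oxidative stress genes had 12 up and 1 down of 16 (12 up and 2 down adjusted over the list alone; adjusted p = 2.44e-05, and adjusted p = 0.0517 with an estimated correlation). Besides Hmox1 these were led by Srxn1 (4.26 ± 0.34), Txnrd1 (3.9 ± 0.16) and Mt1 (3.52 ± 0.25), while Cat (-1.05 ± 0.17), the catalase gene, fell. Stress genes of translation and protein folding had 13 up and 4 down of 19 (the same adjusted over the list alone; adjusted p = 0.000223, and 0.0248 with an estimated correlation), with Gadd45b at 4.21 ± 0.32, Dnajb9 at 3.13 ± 0.19 and Ddit4 at -1.75 ± 0.41. Immediate early genes had 32 up and 1 down of 33, the same adjusted over the list alone (adjusted p = 4.9e-15, and adjusted p = 0.0591 with an estimated correlation). The one down was Klf10 (-0.78 ± 0.29). After background subtraction its fall was no smaller (-0.9), but it was not called (adjusted p = 0.0587). NF-kB and cytokine genes had 15 of 16 up (15 adjusted over the list alone; adjusted p = 0.000131, and adjusted p = 0.232 with an estimated correlation). MAP kinase feedback genes had 11 up and 3 down of 15 (the same adjusted over the list alone; adjusted p = 0.0137, and adjusted p = 0.0564 with an estimated correlation), with Spry1, Etv5 (-1.03 ± 0.14) and Spred2 (-0.57 ± 0.13) falling. YAP and cytoskeleton genes had 15 up and 2 down of 18 (the same adjusted over the list alone; adjusted p = 0.00133, and adjusted p = 0.237 with an estimated correlation), with Thbs1 at 4.56 ± 0.34, Ccn2 at 4.21 ± 0.28 and Amotl2 at -1.45 ± 0.22.

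Lists without a called camera test at T120 also held changed members. Of all listed genes 76.8% were called at T120, and 37.3% were called up. The counts that follow are thus not by themselves a result about a list. Genes regulated by p53 had 8 up and 6 down of 14 (the same adjusted over the list alone; adjusted p = 0.232), with Cdkn1a at 4.84 ± 0.31, Plk3 at 3.7 ± 0.3, Trp53inp1 at -2.79 ± 0.33 and Sesn1 at -2.59 ± 0.19. Glycolysis genes had 10 up and 2 down of 14 (the same adjusted over the list alone; adjusted p = 0.0622), with Hk2 at 4.21 ± 0.31 and Pdk1 at -1.51 ± 0.18. After background subtraction 8 were up and 0 down, and Pdk1 had -0.79 and was not called. Circadian genes had 7 up and 5 down of 16 (the same adjusted over the list alone; adjusted p = 0.985), with Cry1 at 3.65 ± 0.31, Bhlhe41 at -3.29 ± 0.2 and Per3 at -3.14 ± 0.26. Glucocorticoid response genes had 4 up and 5 down of 11 (the same adjusted over the list alone; adjusted p = 0.918; camera placed the list upward at a median of -0.27), with Klf15 at -2.93 ± 0.34, Zbtb16 at -2.88 ± 0.23 and Sgk1 at 2.65 ± 0.18. Replication-dependent histone genes had 6 of 8 down (7 adjusted over the list alone; adjusted p = 0.0545, and 0.582 with an estimated correlation, and 7 down and called with the preset one after background subtraction), with H1f0 at -2.47 ± 0.2, which the symbol rule took although it encodes a linker histone made outside replication. Extracellular matrix genes had 6 up and 2 down of 23 (5 up and 2 down adjusted over the list alone; adjusted p = 0.825), and 6 up and 8 down after background subtraction.

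Markers of other cell types also changed at T120. All 7 measured endothelial markers, of 14 in the list, rose (7 adjusted over the list alone; median 1.7; adjusted p = 0.141, and 0.753 with an estimated correlation, and called with the preset one after background subtraction), among them Cd36 (2.72 ± 0.39), Fabp4 (2.51 ± 0.42), Cdh5 (2.4 ± 0.51) and Kdr (1.7 ± 0.55). Genes in the table had a mean normalized count of at least 98.4 over all libraries, T120 included. A marker low before T120 could thus be measured through a rise there, which favours rising markers. Cd36 was at 3.36 to 19.9 CPM before T120 and 37.1 to 90 CPM at T120. Cdh5, which encodes VE-cadherin, was at 19.2 ± 6.48 CPM at T0, 22 ± 2.98 at T90 and 101 ± 49.4 at T120. Of the smooth muscle and pericyte markers 3 of 8 rose (3 adjusted over the list alone; adjusted p = 0.269), with Rgs5 at 3.36 ± 0.36 and Myh11 at 2.21 ± 0.55. The third was Des, a muscle gene as well, already raised at T30, and Acta2, Tagln, Pdgfrb, Abcc9 and Mcam were not called. After background subtraction 4 rose. Fibro-adipogenic markers had 3 of 7 up (3 adjusted over the list alone), Lox (2.81 ± 0.26), Dcn (1.63 ± 0.51) and Col1a1 (0.92 ± 0.27), with a median of -0.25, a mean of 0.61 and adjusted p = 0.735. After background subtraction the other 4, Dpt, Col3a1, Gsn and Fbn1, were called down (-0.6, -0.53, -0.55 and -0.55). Myofibre markers had 2 up and 7 down of 10 (the same adjusted over the list alone; adjusted p = 0.56), with Acta1 at 2.13 ± 0.47, and 3 up and 4 down after background subtraction. Cd68, the immune marker measured, had 0.72 ± 0.32 (adjusted p = 0.0466), and Chodl, listed as a tenocyte marker, -1.93 ± 0.2. After background subtraction Cd68 had 0.78, no smaller, but was not called (adjusted p = 0.104). The glial markers Pmp22 (-0.16 ± 0.16) and Mbp (0.73 ± 0.41) were not called, although Mbp was called up after background subtraction, where counts under the background were set to 0. In the table were 0 erythroid or mitochondrially encoded genes.

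T120 against T0 called 3003 genes up and 3184 down, a near-even split that TMM scaling favours, with 1494 and 1645 at least 2-fold. After background subtraction 2537 and 2302 were still called in the same direction, and 2925 and 2943 after subtraction of 0.5 of the background. The step from T90 called 734 up and 1117 down, in all 907 without library 90B, 1097 without 90C, 1062 without 120D, and 808 after subtraction.

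Over the whole course the joint F test called 6909 genes. The slope on time was called for 3039 rising and 3261 falling genes. The steepest rises per hour were in Fosl1 (4.38 ± 0.34), Hmox1 (3.44 ± 0.32), Csrnp1 (3.34 ± 0.57), Tnfrsf12a (3.33 ± 0.38), Emp1 (3.29 ± 0.34), Asb5 (3.21 ± 0.26), Fgl2 (3.13 ± 0.23), Pim1 (2.99 ± 0.24), Ier5 (2.82 ± 0.17) and Trib1 (2.76 ± 0.44). The steepest falls were in Tsc22d3 (-2.38 ± 0.25), Muc16 (-2.26 ± 0.76), Nctc1 (-2.19 ± 0.11), Sp110 (-2.16 ± 0.57), Mroh2a (-2.13 ± 0.68), Dbp (-2.11 ± 0.17), Zkscan8 (-2.02 ± 0.15), Sfi1 (-2.01 ± 0.47), G0s2 (-1.99 ± 0.21) and Bmyc (-1.98 ± 0.17). Muc16 and Mroh2a again are background genes. Fos (-0.65 ± 0.86; adjusted p = 0.492) and Egr1 (0.32 ± 0.63; adjusted p = 0.652), which rose early and were lower again at T120, had no called slope. Atf3, highest at T60, had a called one (1.97 ± 0.6; adjusted p = 0.00463).

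The authors' adjusted p-values in the deposited table, per the file headers, were under 0.05 for 87 genes at T15, 609 at T30, 4556 at T60, 5525 at T90 and 6177 at T120. Of these, 54, 361, 4372, 5353 and 6076 were also called here, all in the same direction. Both sets come from the same counts.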

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

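Of the tests for this first pattern, the one on exon length was written before its value was seen, and those on separate expression and on library size were chosen only after the result was seen. Up to T30 the counts moved together also in the 5 long genes of the background measure that had not been noticed in the data beforehand, with a median Spearman rho of 0.923 (10 of 10 pairs over 0.3, and a median of 0.955 without Ryr3), which argues against separate expression of each gene. Genomic DNA carried into the libraries could give such counts: in 1602 thinly covered genes the excess of library 30A over 30C grew with exon length at 0.505 of the expected slope (bootstrap interval 0.358 to 0.649, 1000 draws), which leaves this open. Density in CPM per kb followed the library total over the 11 early libraries (Spearman rho -0.791), but it is divided by that total, and the undivided density had a rho of -0.382 (two-sided permutation p = 0.25 over 100000 permutations), so this cannot tell whether smaller libraries held more background. Apart from separate expression of these genes, no biological explanation was tested.

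For the rise at T120 of the endothelial markers, and of Rgs5 and Myh11 among the smooth muscle and pericyte markers, the tests on other endothelial genes and on the fibro-adipogenic markers were chosen only after the result was seen, and the test on background was written before. No test used the smooth muscle and pericyte markers. A larger share of endothelial cells could explain the rise of 7 of 7 measured endothelial markers (of 14 in the list), but of 7 other endothelial genes, taken from general knowledge, 5 rose, Vwf was not called and Ramp2 fell (-1.78), which leaves this open (6 rose after background subtraction, which had to raise Vwf, and Ramp2 still fell). Both sets hold only genes in the table, which a rise at T120 could bring in. A lower share of the main cell type stays open: the fibro-adipogenic markers had a median of -0.25, but 4 of the 7 started above all endothelial markers at T0, which would hide a small share (these 4 were called down after background subtraction), and the other 3 had a median of 1.63. Subtraction moved the endothelial median from 1.7 to 3.63, which decides nothing on background, since its density was higher at T0 (2.56 CPM per kb) than at T120 (0.384) and subtraction had to enlarge the rise. A change in the endothelial genes within the same cells was not tested.

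For the fall of Tsc22d3, Fkbp5 and Zbtb16 from T15 to T30, the test on the other glucocorticoid genes was chosen only after the result was seen, and the tests on background and on single libraries were written before. Subtraction of the background moved the median of the 3 genes from -1.93 to -2.36, which decides nothing, since its density was higher at T30 (4.47 CPM per kb) than at T15 (1.73) and subtraction had to deepen the fall. Libraries 30A and 30B alone do not account for it, since in 30C, too, 3 of 3 genes lay below every T15 library. There Zbtb16 was at 128 CPM against 379 to 589, and Fkbp5 at 32.8 against 83.1 to 183. For Tsc22d3 the margin was narrow, at 68.3 against 88.9 (15D) to 440. This rests on 30C alone. Loss of glucocorticoid signalling may contribute, but of the 8 other list members 1 fell (Sgk1) and 0 rose, with a median of -0.25, which cannot tell. The whole list of 11 had 4 down and 0 up with a median of -0.64 (camera adjusted p = 0.000113, and adjusted p = 0.44 with an estimated correlation), but 3 of the 4 define the pattern.

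In groups of 4 libraries, a single library stood apart in 6 of 64 checks, where chance gives about 3.2. In T15 library D the TMM factor was 1.16 against 1.06 to 1.07 in the others (gap over range 0.9), and the background density 4.26 against 0.718 to 0.984 (0.9249). In that library Hmox1 was at 5.15 CPM against 2.56 to 2.89 (0.8716) and Fosl1 at 5.32 against 0.632 to 1.08 (0.905). Myc was at 104 CPM in T0 library B against 166 to 179 (0.8294), and at 386 CPM in T60 library C against 596 to 617 (0.9084).

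Neighbouring time points differed by direct tests of the difference, chosen after the data were seen: 394 genes for T30 against T15, 4111 for T60 against T30, 2441 for T90 against T60 and 1851 for T120 against T90. How often other splits of the same libraries called as many genes was a test written before its values were seen. The real grouping called the most for T30 against T0 (1 of 35 splits, 403 genes, highest other 237), T60 (1 of 35, 4533, highest other 0), T90 (1 of 35, 5546, highest other 4029) and T120 (1 of 35, 6187, highest other 0). The same held for T60 against T30 (1 of 35, 4111, highest other 3044), T90 against T60 (1 of 35, 2441, highest other 1433), T120 against T90 (1 of 35, 1851, highest other 998), the F test (1 of 100, 6909, highest other 2606) and the slope (1 of 100, 6300, highest other 8). By shared library letter, a division chosen after the values were seen, 8 splits part all 3 letters as the real one does. Of these, the highest other called 1433 for T90 against T60 and 4 for T120 against T90, and of the splits that part fewer, 594 and 998. For T15 against T0, 3 of 35 splits including the real one called as many (54, highest other 86), so chance was not excluded by the count alone. For T30 against T15 it was also 3 of 35 (394, highest other 1852). The highest split there set 15D, 30A and 30B against the rest, with a difference in background density of 4.31, so it followed the background.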

How the results depend on the processing

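Counts of called genes kept within 1.5 times their value in 134 of the runs under another setting, and in 253 with a library left out. The exceptions follow, and the cause was not tested unless stated. T30 against T0 called 664 genes with the background subtracted, 693 with its density measured without Ryr3, 727 with 0.5 of it subtracted and 147 without the 5 libraries of highest background, which leaves T30 with 1 library. T30 against T15 called 647 with DESeq2, 260 with limma-voom and 69 without those 5 libraries. T60 against T30 called 2370 with subtraction, 2451 with that density and 1619 without those libraries. With subtraction T90 against T60 called 1217 and T120 against T90 called 808 (1229 and 852 without Ryr3); the spread between libraries rose (coefficient of variation 0.309). List tests called were 17 with an estimated correlation, 72 with fry, and 49 in the report. These background settings were chosen after seeing the data.

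Among named genes called with or without subtraction of the background, signs turned with it in these log2 fold changes against T0; signs of genes called in neither fit are not listed. At T60 they were Cd36 1.97, Pdk1 0.24, Rrm2b 0.78, Zmat3 1.19, Fgfr1 -0.01, Ncam1 -0.32, Mbp 6.78 and Kdr 9.07; at T90 Rrm2b 0.57, Zmat3 0.99, Mbp 6.68 and Kdr 9.81; at T120 Rrm2b 0.52, Zmat3 1.35 and Ttn 0. Slopes turned for Rrm2b (0.28) and Zmat3 (0.55). Counts under the background were set to 0, so large values here are not sizes of change. Kdr, for example, was at 8 to 24.6 CPM at T0 and 5.45 to 12.1 CPM at T60 before subtraction. At T30 the quiescence list (adjusted p = 0.0013) and the ribosomal list (adjusted p = 0.792) changed direction. Slopes that turned without T120 were Nid1 -0.1, Tek 0, Pmp22 0.31, Myh11 -0.72, Calcr 0.02, Rgs5 -0.28, Heyl 0.12, Mbp -0.68 and Kdr -0.38, and without T0 Dusp1 -0.39 and Egr1 -0.55. The direction of these slopes thus hung on a single time point. Rgs5, for example, was at 5.03 to 23.9 CPM before T120 and 75.2 to 182 CPM at T120. Egr1 was highest at T30 and lower at T120, so without T0 most of its rise was left out. Of the other values for single genes, 10087 stayed called or stayed uncalled, 163 lost their call and 141 gained one. With a library left out these numbers were 22246, 198 and 128.

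With each library left out in turn the counts ranged from 42 to 66 at T15, 244 to 565 at T30, 4074 to 4612 at T60, 5248 to 5625 at T90 and 5966 to 6226 at T120. They ranged from 6721 to 7039 for the F test, 6165 to 6323 for the slope and 47 to 58 for list tests. For the steps they ranged from 107 to 1140, 3362 to 4216, 1621 to 2514 and 907 to 2093, in order of time. With the library letter as a block the counts were 53, 394, 4558, 5576 and 6182 against T0, 368, 4053, 2507 and 1617 for the steps, 6901 and 6293 for the F test and slope, and 52 list tests. With T60, T90 and T120 alone, where same-letter libraries deviated together, the block gave 2810 and 1651 for the late steps, of which 2208 and 1361 were called without it too. The report names no gene or list for these steps whose call the block changed. Over all times 26 of 51 same-letter pairs had a residual correlation over 0.1 (median 0.116, and -0.0208 for other letters), and 10 of 22 libraries matched their own letter best. The other low-count filters removed 0 of the genes tested, and the pseudocount alternative was not run, since it applies to normalized values. Of simulated 1.5-fold changes, 24 of 80 were found at T15, 12 of 73 at T90 and 20 of 62 at T120. Few genes were changed in those runs, unlike the data at T90 and T120.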

Other observations

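Some single genes had the following time courses, and differences in timing between genes were not tested. Dtx4 fell by 0.55 on the log2 scale at T60 (SE 0.12; adjusted p = 0.000469), and Hes1 had 0.02 ± 0.31 at T60 and -1.53 ± 0.35 at T90. Notch3 had 0.41 ± 0.14 at T60 (adjusted p = 0.0168; 0.03 and not called after background subtraction) and -0.33 ± 0.14 at T120 (adjusted p = 0.035). Spry1 fell between T60 and T90 (-1.19 ± 0.23) and had -0.09 ± 0.23 in the next step, while Calcr had -0.22 ± 0.15 and then fell (-0.77 ± 0.15). Cebpb, a transcription factor gene of inflammation, rose at T60 (3.8 ± 0.35), fell from T60 to T90 (-1.43 ± 0.35) and rose again to T120 (1.37 ± 0.35). The fall and the second rise share the T90 libraries, so a low T90 mean alone would give both.

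At T120 Hk2 (4.21 ± 0.31), Slc2a1 (2.56 ± 0.32), the glucose transporter gene, Pfkp (2.3 ± 0.16) and Pdk4 (2.02 ± 0.19) rose, and Pfkfb3 (-0.63 ± 0.22) and Pdk1 (-1.51 ± 0.18) fell, but these falls were not called after background subtraction (-0.6 and -0.79).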
